A study of Zea mays subsp. mays with 8 samples.

How the data were processed

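CAGE libraries were made from shoots and roots of 14-day-old maize seedlings of the inbred lines B73 and A632, with 2 libraries in each of 4 groups. Seedlings grew with 16 h of light at 27 °C and 8 h of darkness at 21 °C, and the tissue of 5 seedlings was pooled per library, per the labels' protocols. From 5 µg of total RNA, cDNA was primed at random, capped molecules were biotinylated and captured on streptavidin, and the enzyme EcoP15I released 27 bp from the 5′ end, per the labels' protocols. B73 root libraries were amplified for 16 PCR cycles and all others for 14, per the labels' protocols, so this difference cannot be separated from the B73 root group. The tags carry no molecular identifiers in these protocols, so copies made by PCR count as tags. The libraries were barcoded, pooled and sequenced on an Illumina HiSeq 2000, per the labels' protocols.

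Bowtie2 2.0.4 is named, per the submitters' processing notes. The genome build, the clustering tool, its thresholds and the libraries that make up each set are not given in the sources used here. The deposited files hold 75681 start-site clusters in 4 sets, each with coordinates, strand, signal, dominant site, the positions of the 10th and 90th signal percentiles and a shape score. All 75681 clusters matched in name and position between the files. The deposited signal is a value normalized by the authors to a power law. The values at dominant sites of each set equal a constant times the tag number raised to an exponent, which was 1.09 in B73 root and 0.888 in B73 shoot. A single tag was worth 0.133 in root and 0.266 in shoot. Inverting the law gave whole tag numbers for 100% of dominant sites within 0.01 tags. The deposited score is not named in the files. For clusters of 2 positions it equalled 2 plus the sum of p log2(p) over tag shares p within 0.002 in 100% of cases, and it was 2 for clusters of 1 position. From normalized signal in place of tags, that match fell to 24.5% in root and 18.2% in shoot, so the score follows tags. Interquantile widths were not recomputed, so whether they follow tags or normalized signal was not checked. The highest cluster numbers in the names, 37028 in root and 42556 in shoot, exceed the clusters listed, so each set is part of a longer list.

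Sets were assigned to groups by name. The 2 sets named B73 match the B73 root and B73 shoot labels. The other 2 sets are named Mo17, another maize line, while the labels name A632, and they entered no comparison. The columns carry no library or replicate, so no count model and no test across replicates was possible. Intervals cover counting error only, with tags or clusters taken as independent.

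The comparison rules were fixed before the data were examined. They foresaw TPM values, and the same numbers were applied to the signal instead. Root and shoot clusters on the same strand were joined with bedtools 2.31.1 where they overlapped by at least 1 bp, and clusters overlapping exactly 1 partner in both directions formed pairs. A pair was called higher in a tissue when the higher signal was at least 1 and the difference was at least 4-fold on log2(signal + 1), which understates the change of weak clusters. The named pairs are the 5 with the largest log2 difference in each direction. The strongest clusters of each set and the clusters without a partner were ranked by signal, and these rankings and the ranking by distance between dominant sites were added later. Lists of genes had also been fixed, but none could be scored because the files pair no cluster with a gene. Initiator sequence and position relative to genes were not analysed here, since no genome of the files' build was used.

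Sharp clusters had an interquantile width of at most 10 bp among clusters with a signal of at least 1. Shares have 95% Wilson intervals and ratios of tags have 95% exact binomial (Clopper-Pearson) intervals. Divergent sites were counted within 500 bp, also after each of 100 shuffles of strand within chromosomes. Dense runs, the scale of recovered tags and comparisons of dominant sites and shape between tissues were added after the data had been seen. The tags of a whole cluster were bounded by the tags at its dominant site divided by that site's share of the signal, which is a lower bound in root and an upper bound in shoot given their exponents. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The pairing and the size rule were tested on simulated data made from 19880 clusters of B73 shoot with 200 clusters changed 16-fold. All 129 changed clusters with a signal of at least 5 that could be paired were recovered, with 0 false calls. Tags were recovered in 100% of simulated sites. The simulated noise had a standard deviation of 0.2 on the natural log scale, which is small against the size rule. The simulation therefore cannot show how many false calls the comparison of root with shoot holds. Alternatives changed the signal minimum, the fold, the pseudocount, the normalization, the pairing, the width limit, the distance for divergent sites and the tag minimum.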

Results

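Transcription start sites were mapped by cap analysis of gene expression (CAGE), which captures the capped 5′ ends of transcripts and sequences a short tag from each. The source was 14-day-old maize (Zea mays subsp. mays) seedlings of B73 and A632, which are inbred maize lines. Shoots and roots gave 4 groups of 2 libraries, 8 libraries in all, and each library came from 5 pooled seedlings. The files hold 1 value per start-site cluster and set, with no value per library, so the spread between replicates could not be measured and no difference below has a replicate check. The B73 root set held 14568 clusters with a summed normalized signal of 492155, and the B73 shoot set held 19880 clusters with 509605. Behind the dominant (strongest) sites of these clusters stood 1267305 tags in root and 2394924 tags in shoot, as recovered from the normalized values. Coordinates are those of the files, whose genome build is not given in the sources used here, and no cluster carries a gene name, so regions are named by position.

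The question of where transcription starts in each tissue was addressed first. B73 clusters lay on all 10 chromosomes, with the highest number on chromosome 1, which held 2372 (16.3%) in root and 3216 (16.2%) in shoot. The fewest root clusters were on chromosome 10 (938) and the fewest shoot clusters on chromosome 8 (1443). The plus strand held 49.6% of root clusters (95% Wilson interval 48.8 to 50.4) and 50.9% of shoot clusters (50.2 to 51.6). The same region led both sets, on the plus strand of chromosome 4 with its dominant site at 1079094. In root this cluster spanned 1079052 to 1079190, had a signal of 73498 and took 14.9% of the set's signal. In shoot it spanned 1079086 to 1079103, had a signal of 8177 and took 1.60%.

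The next strongest cluster was also shared. It had its dominant site at 18759495 on the minus strand of chromosome 2, with a signal of 52751 in root and 4743 in shoot. In root, 97.7% of its signal fell on that single position, and in shoot 86.2%. Root then had clusters with dominant sites at 34240659 on chromosome 10 (plus strand, signal 17090), 152459616 on chromosome 4 (minus strand, 16008) and 178504715 on chromosome 1 (minus strand, 3171). Shoot then had 213701400 on chromosome 1 (minus strand, 3954), 103448299 on chromosome 9 (minus strand, 2542) and 10200807 on chromosome 10 (minus strand, 2465). Root signal was concentrated in fewer regions than shoot signal, through its few strongest clusters. The 2 strongest clusters took 25.7% of the root signal against 2.54% of the shoot signal. The 10 strongest took 35.7% against 6.55%, and the 100 strongest 51.1% against 24.5%. By recovered dominant-site tags, the 2 strongest took 18.3% in root and 4.47% in shoot. The 10 strongest took 26.8% and 11.5%, and the 100 strongest 43.0% and 35.4%. The power-law exponent, 1.09 in root and 0.888 in shoot, widens the contrast on signal. The B73 root libraries were amplified for 16 PCR cycles and the others for 14.

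Start regions were narrow in both B73 tissues. A cluster was called sharp when the stretch between the 10th and 90th percentiles of its signal was at most 10 bp. Of 13234 root clusters with a signal of at least 1, 55.7% were sharp (95% Wilson interval 54.8 to 56.5), and of 19764 shoot clusters, 53.4% (52.7 to 54.1). Median widths were 7 bp in root and 8 bp in shoot. Sharp clusters held 82.1% of the root signal and 58.0% of the shoot signal. In root the share of sharp clusters was higher in each step of dominant-site tags, from 39.7% of 1502 clusters below 5 tags to 96.2% of 130 with at least 1000. In shoot it did not follow a single order. It was 66.0% of 235 clusters below 5 tags, 39.4% from 5 to below 10, 56.7% from 20 to below 50, 54.4% from 50 to below 100, 62.7% from 100 to below 1000 and 77.9% of 298 clusters with at least 1000. A sharp cluster puts more of its tags on its dominant site, so a rise over these steps is partly built in. Clusters of 1 position, which are always sharp, were listed only from 18 tags in root and 16 in shoot. The steps below 10 tags therefore held none of them. From 20 to below 50 tags they made up 20.0% of root and 32.5% of shoot clusters. By signal of the whole cluster, the share was 55.2% in root and 48.2% in shoot at 5 or more. At 10 or more it was 56.3% in root and 45.3% in shoot. Without clusters lying in a dense run of either tissue (described further on), the share was 43.2% in shoot and 53.5% in root. Across clusters, Spearman's rho between signal and width was -0.018 in root and 0.168 in shoot, and clusters are not independent replicates.

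**Figure D1:**
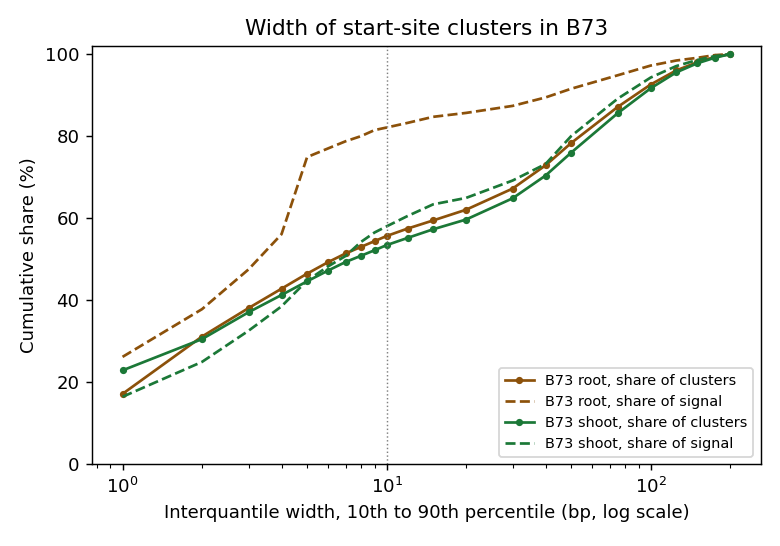
Cumulative share of start-site clusters (solid lines with points) and of signal (dashed lines), in percent, against the interquantile width in bp on a log axis, for B73 root (brown) and B73 shoot (green) clusters with a signal of at least 1. At the dotted line of 10 bp the clusters stood at 55.7% in root and 53.4% in shoot, and the signal at 82.1% and 58.0%.

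Root and shoot of B73 were then compared, a comparison between tissues that the study's design names. Most start regions of root were also used in shoot. Of the root clusters, 12789 (87.8%, 95% Wilson interval 87.2 to 88.3) overlapped a shoot cluster on the same strand by at least 1 bp, and of the shoot clusters, 13200 (66.4%, 65.7 to 67.1) overlapped a root cluster. The 1779 root clusters without a partner held 3.42% of the root signal, and the 6680 such shoot clusters held 15.003% of the shoot signal. Among clusters with a signal of at least 100, 96.6% of 534 in root and 90.9% of 691 in shoot had a partner. The share was lowest at signals from 2 to below 5, with 77.2% of 3992 in root and 47.2% of 6258 in shoot. Below a signal of 1 it was 98.6% of 1334 in root and 99.1% of 116 in shoot, so the weakest clusters were listed almost only where the other set had a cluster. The strongest cluster listed in root alone lay at 110499026 on the plus strand of chromosome 1, with a signal of 746 and 2724 tags at its dominant site. It was followed by 24676039 on the minus strand (signal 404) and 49283980 on the plus strand (237) of the same chromosome. In shoot alone the strongest lay at 146189960 on the minus strand of chromosome 6, with a signal of 1728 and 18765 tags. It was followed by 368035 on the plus strand of chromosome 1 (1521), inside a dense run, and 215555223 on the minus strand of chromosome 3 (927). A cluster missing from a list is not shown to be silent, since each set lists only clusters that passed the authors' thresholds.

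Signal differed widely between the tissues at shared regions. The 12356 clusters that overlapped 1-to-1 were compared on log2(signal + 1), and a fixed size of at least 4-fold stood in for a test. By that rule 532 pairs were higher in root, 1916 were higher in shoot and 9908 were neither. The split depended on the scale and on weak partners. Below a signal of 1, 1315 root clusters but 115 shoot clusters overlapped the other set, so weak partners were mostly root clusters. How much of the split this made was not tested. With a signal of at least 5 in both tissues, 268 pairs were higher in root and 292 in shoot (52.1%). The authors' normalization follows a power law whose exponent was 1.09 in root and 0.888 in shoot. Of the pairs beyond 4-fold, 78.3% were higher in shoot on the deposited signal. That share was 53.2% after quantile normalization, 59.9% with totals that left out the 10 strongest clusters, and 42.9% (1467 pairs higher in root, 1101 in shoot) on recovered dominant-site tags per 1000000 of the set. The median log2 difference of root minus shoot moved from -0.50 on the deposited signal to 0.46 on recovered tags. Pairs beyond 4-fold on both of these scales numbered 517 with root higher and 1074 with shoot higher. Across pairs Spearman's rho of the signals was 0.435.

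On the deposited signal, the pair with the largest excess in root had its root dominant site at 11211520 on the minus strand of chromosome 1. Its signal was 1121 in root and 0.531 in shoot, a log2 difference of 9.52. Its dominant sites, 1 bp apart in the 2 tissues, had 1506 tags in root and 1 in shoot, which is 2846 times as many for the set's total (95% exact interval 510.03 to 112485). Such intervals take tags as independent, while copies made by PCR count as tags. They also leave out that these pairs were picked for their extreme values. Next came 191964278 on the minus strand of chromosome 5, with a signal of 1181 against 0.970 and a log2 difference of 9.23. It was followed by 240779577 on the plus strand of chromosome 4 (9.02), 130544761 on the plus strand of chromosome 3 (8.66) and 203693327 on the minus strand of chromosome 1 (8.36). The pair with the largest excess in shoot had its dominant site at 7276404 on the plus strand of chromosome 3. Its signal was 1.42 in root and 2197 in shoot, a log2 difference of -9.83. That site had 8 tags in root and 24060 in shoot, which is 1591 times as many in shoot for the set's total (95% exact interval 807.6 to 3687). Next came 1341316 on the minus strand of chromosome 6, with a signal of 0.575 against 893.3 and a log2 difference of -9.15. It was followed by 83469802 on the plus strand of chromosome 10 (-9.07), 12613552 on the minus strand of chromosome 3 (-9.04) and 16219765 on the minus strand of chromosome 10 (-8.77). All 10 of these pairs had the same direction by recovered tags scaled to the set's total, but their order differed on that scale. Recovered tags come from the same deposited values, and differences this large leave no room for a change of sign, so the shared direction is no separate evidence. Among the strongest shared regions, 34240659 on chromosome 10 was higher in root by a log2 difference of 4.77 and 213701400 on chromosome 1 was lower in root, at -7.78. At 156319503 on the minus strand of chromosome 6 the root signal was 2937 and the shoot signal 685.0, while the tags at the dominant sites were 6541 and 6587, or 1.88 times as many in root for the set's total (1.81 to 1.94).

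**Figure D2:**
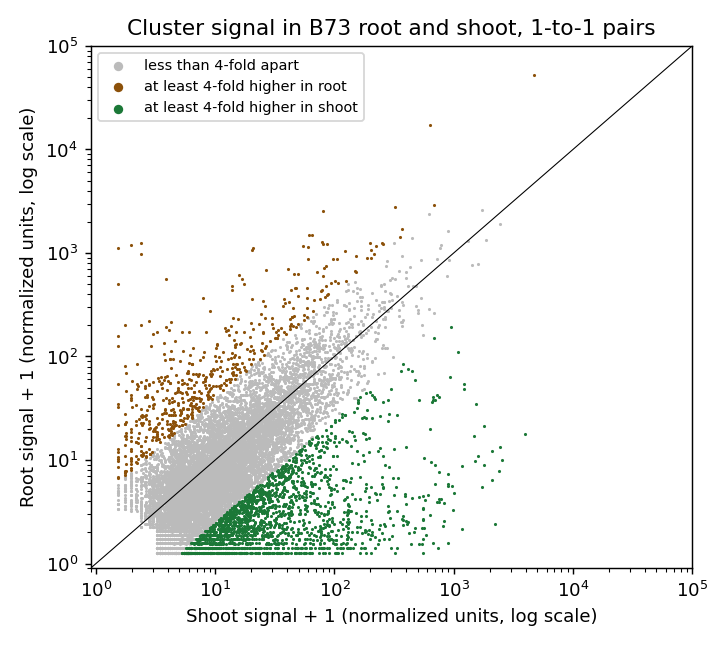
Each point is 1 of the 12356 cluster pairs of B73, with shoot signal + 1 on the horizontal and root signal + 1 on the vertical axis (normalized units, both axes log). Brown points are the 532 pairs at least 4-fold higher in root, green points the 1916 at least 4-fold higher in shoot, grey points the other 9908, and the line marks equal values. On recovered tags scaled to each set's total the counts were 1467 and 1101.

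Whether both tissues started transcription at the same base was examined in the same pairs. The dominant site was at the same position in 6079 of 12356 pairs (49.2%, 95% Wilson interval 48.3 to 50.1). It was 1 to 10 bp away in 29.4% of pairs and more than 10 bp away in 21.4%, with distances taken without regard to direction. Pairs with many tags shared the site more often. With at least 100 tags in both tissues, 73.8% of 961 pairs had the same site (70.9 to 76.5), 23.7% were 1 to 10 bp apart and 2.50% (1.68 to 3.69) were more than 10 bp apart. Of these 961 pairs 629 were sharp in both tissues, and sharp clusters leave little room for wider separations. In pairs broad in both tissues, sites more than 10 bp apart made up 39.9% of 5666 and, with at least 100 tags, 10.1% (6.63 to 15.1) of 198. With at least 1000 tags, 83.6% of 55 pairs had the same site and 0 lay more than 10 bp apart, for which the interval reaches 6.53%. The 5 pairs with the widest separation among those with at least 100 tags were picked out after their values had been seen. On the plus strand of chromosome 4 the dominant site was 212126625 in root (266 tags) and 212126445 in shoot (114 tags), 180 bp apart. On the minus strand of chromosome 2 it was 111530399 in root and 111530273 in shoot, 126 bp apart. On the plus strand of chromosome 3 it was 1711675 in root and 1711797 in shoot, 122 bp apart. On the plus strand of chromosome 8 it was 90087684 in root (1405 tags, 96.1% of the cluster's signal) and 90087577 in shoot (442 tags, 72.0%), 107 bp apart. On the plus strand of chromosome 1 it was 88349121 in root and 88349225 in shoot, 104 bp apart.

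**Figure D3:**
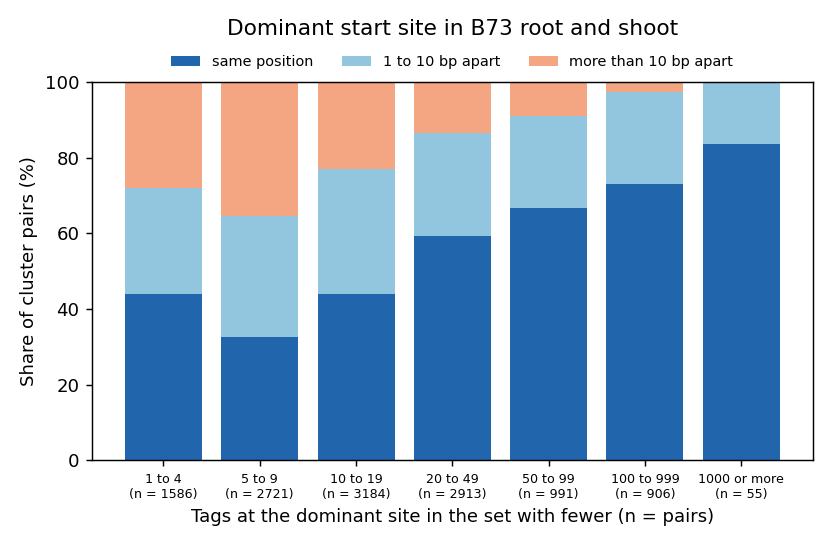
Share of B73 cluster pairs, in percent, whose root and shoot dominant sites were at the same position (dark blue), 1 to 10 bp apart (light blue) or more than 10 bp apart (orange), by the number of tags at the dominant site in the set with fewer tags. The number of pairs stands under each bar. The orange part is 35.3% at 5 to 9 tags, 2.65% from 100 to below 1000 and 0% at 1000 or more.

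The shape of the start region was mostly shared between root and shoot. Both clusters of a pair were sharp in 4639 pairs and both were broader than 10 bp in 5666, so that 83.4% of pairs kept their class. A further 1588 pairs were sharp in root alone and 463 in shoot alone, a ratio of 3.43. Median widths over all pairs were 10 bp in root and 23 bp in shoot. The 121 pairs sharp in root alone against 13 in shoot alone with at least 100 tags in both tissues give a ratio of 9.31. With the authors' shape score above -1 as the definition of sharp, the counts were 1104 and 581, a ratio of 1.90. The median shape score was 0.187 in root and 0.068 in shoot over all pairs and 0.236 and 0.203 with at least 20 tags, the order of the widths. With at least 100 tags it was 0.506 and 0.565, the opposite order to the widths (3 bp and 5 bp).

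Divergent start sites, where a minus-strand site lies upstream of a plus-strand site within 500 bp, were counted in B73. In root 54 of 6549 plus-strand sites (0.825%, 95% Wilson interval 0.633 to 1.07) had such a partner, and in shoot 887 of 10055 (8.82%, 8.28 to 9.39). In 100 random reassignments of strand within chromosomes the median shares were 6.78% and 21.9%. Reassignment breaks up neighbouring clusters on the same strand, which raises its shares, so it does not show whether divergent sites were fewer than chance gives. Without clusters in dense runs the shares were 0.845% in root and 1.49% in shoot. A neighbour on the same strand within 500 bp was found for 10.9% of root clusters and 27.4% of shoot clusters.

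Part of the shoot clusters lay in dense runs. These were defined, after the clusters had been examined, as at least 10 clusters of a set whose neighbouring dominant sites were at most 2000 bp apart. Shoot had 97 runs with 4018 clusters, 20.2% of its clusters and 22.9% of its signal. Root had 33 runs with 801 clusters, 5.50% of its clusters and 2.45% of its signal, and 31 of them overlapped a shoot run. Clusters of a shoot run lay almost entirely on the same strand, with a median of 96% on the main strand. The largest shoot run, at 90145745 to 90152635 on chromosome 10, held 206 clusters. The next held 199 at 165543583 to 165550472 on chromosome 3, 195 at 210028089 to 210034133 on chromosome 5 and 190 at 172733928 to 172740599 on chromosome 2. The largest root run, at 234655949 to 234660886 on chromosome 1, held 105 clusters, and the shoot run at that place held 107. Regions of shoot runs held 2.60% of the root signal. Where runs were left out, all clusters inside a run of either tissue were removed, 1012 in root and 4029 in shoot.

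**Figure D4:**
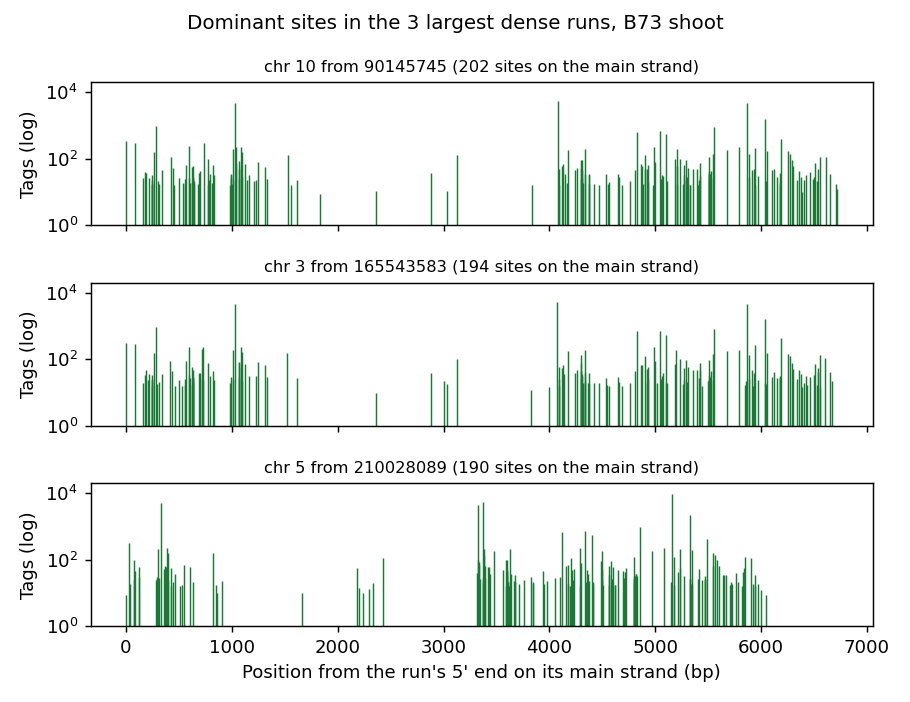
Dominant start sites on the main strand of the 3 largest dense runs of B73 shoot, on chromosomes 10, 3 and 5, each drawn from its 5′ end in bp, with the tags at each site as the height of a line on a log axis. The first 2 runs share 83.0% of the sites of the smaller run at the same spacing.

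The study's design also names root against shoot in A632 and A632 against B73 in each tissue. These comparisons, and the difference of the tissue effect between the lines, were not made, because the other 2 sets in the files carry a line name that is in none of the sample labels.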

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

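The tests of splitting, tag depth and dense runs behind the cluster number, of strong sites within runs, of few tags behind differing dominant sites, and of whole-cluster tags behind the widths were chosen only after the result was seen. Those of shared copies, of the exponent and of dominant-site tags behind the widths were set out before.

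The set named Mo17_R held 18358 clusters, and the set named Mo17_S held 22875. They stand out as data outside the comparisons, since the labels name A632 and no Mo17, and a set with no clusters would give 0. Of the clusters with a signal of at least 1, 50.6% (95% Wilson interval 49.9 to 51.4) were sharp in Mo17_R and 54.7% (54.0 to 55.3) in Mo17_S.

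B73 shoot had 1.36 times as many clusters as B73 root, with 20.2% of them in dense runs. Leaving out all clusters inside a run of either tissue (1012 in root, 4029 in shoot) gave a ratio of 1.17, and counting clusters within 500 bp on the same strand once gave 1.15, so each lowered the excess without removing it and stays open as part of it. Tag depth may account for it, because at 50 or more dominant-site tags per 1000000 outside the 10 strongest sites the ratio was 0.825 (3409 clusters in root, 2812 in shoot). That scale counts dominant sites alone, and dense runs held 27.6% of these tags in shoot and 3.28% in root. At deposited signals of at least 5 and of at least 10 the ratio was 1.68, so depth stays open as well. For the runs themselves, tags shared between near-identical copies are a candidate explanation. Of the 45 pairs among the 10 largest runs, 30 had the majority of the smaller run's sites in common at 1 offset. Strong sites together with the sites within 3000 bp downstream of them made up 13.1% of run clusters. That left weaker sites beside strong ones open as an explanation. A difference between tissues in the transcription of such copies was not tested.

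Dominant sites differed between root and shoot in many pairs. Few tags may account for part of the separations of more than 10 bp, whose share was 21.4% over all pairs and 2.50% with at least 100 tags in both tissues. Because sharp clusters are more frequent among the latter, pairs broad in both tissues bear on it more directly, and their share went from 39.9% to 10.1% (6.63 to 15.1), which leaves open how much few tags account for. The same explanation is argued against as the whole cause of separations of 1 to 10 bp. Their share went from 29.4% over all pairs to 23.7% with at least 100 tags. In pairs sharp in both tissues it went from 39.6% to 23.1%, so few tags stay open for part. In pairs broad in both it went from 19.6% to 21.7%, but wider separations became rarer there, so that rise does not bear on few tags. Such broad pairs numbered 1111 against 2297 with the same site, and 43 against 135 with at least 100 tags. Neighbouring positions of nearly equal use, which chance could exchange at any depth, and a difference between tissues stay open and were not tested. Chance exchange would move the site either way alike. Distances were taken without direction, so whether shoot sites lay mostly upstream or mostly downstream of root sites was not examined.

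Pairs sharp in root alone outnumbered those sharp in shoot alone 3.43 to 1. Fewer tags in root are argued against as the whole cause, since the ratio was 3.63 (697 against 192) in the 4888 pairs with at least as many dominant-site tags in root and 2.20 (1.87 to 2.58, 95% exact interval) in the 4232 pairs with at least as many tags in the whole cluster. The larger power-law exponent of root, which would narrow widths if they were taken on normalized signal, may contribute. The score computed on tags was higher in root in 53.4% (52.5 to 54.2) of 11936 pairs, between the 52% and 60% set as limits. Scores also favoured root in 57.4% (55.9 to 58.8) of 4673 pairs with at least as many dominant-site tags in root. Choosing pairs by those tags favours root clusters with more of their tags on that site, which raises the score. Pairs above -1 in a single tissue numbered 1104 in root and 581 in shoot, without tags being matched. With at least 100 tags in both tissues they numbered 24 and 11, but the median score was 0.506 in root and 0.565 in shoot. Whether part of the excess remains without the exponent therefore stays open, and a narrower start region in root tissue cannot be told apart. The 16 PCR cycles used for B73 root alone cannot be told apart from the tissue either.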

How the results depend on the processing

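Alternatives on recovered tags, totals without the 10 strongest clusters, merging, pairing, tag minimums, the shape score, dense runs and the signal minimum of the overlap were chosen after seeing the data, and the others before. Of 106 alternative values, 50 stayed close to the reported value, 55 moved and 1 reversed. A reversal was scored only for ratios and for the share of calls higher in shoot. A changed order of the tissues in other shares, as by full width below, counted as moved. The cluster-number ratio of 0.825 at the threshold scaled to tags was not among the 106. Close meant within the interval for shares and within 1.5 times for counts and ratios. For the share of calls higher in shoot it meant within 10 percentage points. Filters and limits move counts and shares by their own construction, and elsewhere the cause was not tested. No paired analysis was possible because the columns carry no replicates. For the same reason no replicate was left out and no other model was run. Leaving out organelle clusters removes nothing because 0 are listed. All listed B73 clusters lie on the 10 chromosomes, so whether tags of organelle RNA are among them could not be checked.

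The ratio of shoot to root cluster numbers was 1.15 to 1.68 over the signal minimums, merging and omission of dense runs, but 0.825 at the threshold scaled to dominant-site tags. Clusters numbered 7854 in root and 13164 in shoot at a signal of at least 5, and 4854 and 8143 at 10. The share of sharp clusters was 46.5% in root and 44.6% in shoot with a 5 bp limit, 62.1% and 59.7% with 20 bp, 51.1% and 41.9% without clusters of 1 position, 41.6% and 47.3% by full width, 87.1% and 86.9% by shape score above -1, and 53.5% and 43.2% without dense runs. It was 54.6% in root over all clusters, and 48.2% and 45.3% in shoot at signals of at least 5 and 10. Full width put shoot above root.

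Divergent partners were found for 0.382% of root and 4.82% of shoot sites within 250 bp, 1.13% and 11.4% within 1000 bp, and 0.414% and 3.50% at a signal of at least 5. The share was 1.18% in root over all clusters and 1.49% in shoot without dense runs. Overlap was 90.5% in root and 74.6% in shoot at a signal of at least 5, and 96.3% and 88.4% at 50. Without dense runs it was 75.7% in shoot.

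Pairs higher in root and in shoot numbered 1549 and 4353 at 2-fold, 222 and 897 at 8-fold, 338 and 881 with a pseudocount of 5, and 299 and 884 with the same dominant site. With a signal of at least 5 in both tissues they were 268 and 292 (52.1% in shoot), and after quantile normalization 967 and 1101 (53.2%). Without the 10 strongest clusters in the totals, 1105 pairs were higher in root and 59.9% of calls in shoot. On recovered tags per 1000000 the split reversed, with 1467 and 1101 (42.9%). This scale undoes the power law and counts the dominant site alone, and which of these turned the split was not tested.

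Pairs with the same dominant site made up 63.7%, 73.8% and 83.6% at 20, 100 and 1000 tags or more in both tissues. The ratio of pairs sharp in root alone to those sharp in shoot alone was 9.31 at 100 tags and 1.90 by shape score. The median dominant site had 19 tags in root and 25 in shoot, which limits how precisely its position is known.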

Other observations

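The test of shared copies described here was set out before its result was seen, after the runs had been found.

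Within the 10 largest dense runs of B73 shoot, the highest share of sites matched at 1 offset was 83.0%, between the runs on chromosome 10 at 90145745 and chromosome 3 at 165543583. Randomly placed sites matched at most 15.9%. In the 30 pairs of runs with the majority of the smaller run's sites in common, the matched sites had similar tags, with a median Spearman's rho across sites of 0.936 and a median of 91.6% of sites within 1.5-fold. These pairs involved 9 of the 10 runs. The run at 234655943 to 234660887 on chromosome 1 was the exception, with 9.52% to 11.4% of sites matched to the others, and it was the run that root held at similar size.

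Clusters of a single position made up 55.7% of shoot clusters in runs and 10.6% of those outside, and 27.7% and 7.27% in root. Every such cluster had at least 18 tags in root and 16 in shoot. Of the shoot clusters in runs, 29.6% overlapped a root cluster, and of the root clusters in runs, 80.8% overlapped a shoot cluster.

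The set named Mo17_R had a summed signal of 618722 and 2797561 tags at dominant sites, with 41.1% of its signal in its 100 strongest clusters. The set named Mo17_S had 602151, 3409185 and 23.7%.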
